A study of Saccharomyces cerevisiae with 7 samples.

How the data were processed

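Total RNA of the wild-type yeast strain CEN.PK113-7D, a prototrophic laboratory strain used for physiological work, was measured on 7 single-channel oligonucleotide arrays. Per the labels, the cells grew aerobically in batch on 20 g/L galactose, and lithium chloride (LiCl) was added to 10 mM in the exponential phase, at a biomass of 3 g dry weight per litre. Arrays were grouped by the time in their labels. Of these, 3 arrays were taken just before the addition and 1 array each at 20, 40, 60 and 140 min after it. The labels number the 3 samples before LiCl as replicates but do not say that they came from separate cultures. The spread between them, on which the p-values rest in whole or in part, may therefore be technical. The labels name no culture without LiCl at the later times and no mock addition, so LiCl and time in culture go together.

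The deposited values are array intensities on a linear scale, 1 value per probe set and array, with none below 0. The software that made the authors' intensities is not given in the sources used here, and neither are detection calls. The values themselves show a global scaling: the mean of each array without the lowest and highest 2% of probe sets lay between 500.337 and 500.527 on the 7 arrays. Because these trimmed means differed so little, the deposited intensities were used without further normalization between arrays, by a rule set before the data were examined. The number of arrays limits the precision, and the arrays give no count or depth.

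The table held 9335 probe sets. The platform annotation gave exactly 1 gene for 6504 of them, several genes for 328 and none for 2443, and 60 were array controls. Symbols were updated through gene identifiers to the RefSeq annotation of assembly R64, used for names alone. Probe sets with several genes or none were left out of the gene tests. Of several probe sets of a gene the brightest was kept, which gave 5656 genes. Intensities under 20.9, the 20th percentile of all values, were set to that floor before log2 was taken, and the 5405 genes whose mean intensity over the 7 arrays lay above the floor were tested. A fold change of a gene with values at the floor is therefore understated. It was written as a lower bound where all arrays of a group were at the floor, which applied to 15 genes before LiCl and 6 genes after it. For 247 tested genes the probe set's name marks sequence that is shared with or similar to another gene, and their values are uncertain among paralogs.

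Tests were run in R 4.3.3 with limma 3.58.1 (lmFit and eBayes with an intensity trend), two-sided, with Benjamini-Hochberg adjustment. A gene was called at an adjusted p under 0.05. The 4 arrays after LiCl were compared as 1 group with the 3 arrays before it, with 5 residual degrees of freedom. No time after LiCl had a replicate, so the 4 times served as replicates of that group, and they may come from 1 culture. The spread in this comparison therefore holds the time course too. It favours genes that stay changed, and genes that change gradually are more easily missed. In a second fit each time was its own level, so that its 2 residual degrees of freedom came from the arrays before LiCl alone and each lone array was assumed to vary like them. That fit gave the contrast of each time against before LiCl, an F-test over the 4 times and the direct contrast of 140 against 20 min. Errors given with log2 changes are limma's standard errors (SE). Errors given with intensities are standard deviations (SD) over the 3 arrays before LiCl, and each later time has a single array.

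Before the data were examined, 29 gene lists were fixed from general knowledge of yeast. Each was tested against all other tested genes with limma's camera, at a preset inter-gene correlation of 0.01 and again with an estimated correlation, with Benjamini-Hochberg adjustment over the lists, or over lists and times. Genes named in the text followed a rule fixed at the same time. It took the 12 largest rises and 12 largest falls among genes called in the grouped comparison whose 4 LiCl arrays all lay on the same side of the arrays before LiCl. It also took the 4 largest rises and 4 largest falls among the genes called at each time, and up to 4 members of each list with the largest change. A fixed set was always named: GAL1, GAL2, GAL3, GAL4, GAL7, GAL10, GAL80, PGM1, PGM2, UGP1, MET22, INM1, HAL1 and, as a reference, ACT1. ENA1 belonged to that set and was not analysed here by itself. A slope on log2 time within the 4 LiCl arrays, and lists of mitochondrial ribosomal proteins, iron supply, phosphate starvation and endoplasmic reticulum folding, were added after the data had been seen.

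The fits were tested on simulated data: arrays were drawn from the gene means before LiCl and the fitted spreads, with 200 of the 5405 genes changed. In the grouped comparison, 85% of the 2-fold and 100% of the 4-fold changes were recovered, with 17 unchanged genes among 202 calls. At 20 min the shares were 27% and 98%, with 11 unchanged genes among 136 calls. At 140 min they were 29% and 95%, with 16 among 140. In each comparison the share of unchanged genes among the calls was above the threshold of 0.05. The drawn arrays held no time course after LiCl and no correlation between genes. Lone arrays were drawn to vary like the arrays before LiCl. The rates therefore describe the simulated data and need not hold for the real arrays. The alternatives tried were quantile normalization, scaling of arrays to a common median, floors at the 10th and 40th percentiles, an offset in place of the floor, no filter and a filter at 3 times the floor, a variance model without trend, plain probe sets alone, and leaving out each array in turn. For the lists an estimated correlation and leaving out genes of more than 1 list were tried as well. Fits with the ACT1 ratio, the TBP ratio or the 25S ribosomal RNA signal as a covariate, an estimated correlation for the lists by time, and G2/M without SWI4 were added after the data had been seen. Figures were drawn with matplotlib 3.10.9.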

Results

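Transcript levels of galactose-grown yeast were followed from just before to 140 min after the addition of 10 mM LiCl, to describe how the cells respond to the salt. Levels of 5405 genes were compared between 3 arrays before LiCl and 4 arrays taken at 20, 40, 60 and 140 min. The arrays before LiCl differed among themselves with an SD of the log2 difference of 0.44 to 0.48 over genes, and 3.55% to 4.88% of genes differed by over 2-fold between any 2 of them. Against these arrays, the SD lay between 0.75 and 0.83 at 20 min and between 1.03 and 1.12 at 140 min. ACT1, the actin gene used as a reference, had an intensity of 9791 ± 1847 (SD, n = 3) before LiCl and 9328 on average after it, with a log2 change of -0.05 ± 0.17 (SE; 0.31 after quantile normalization, which turns the sign). The ratio of 3' to 5' signal of ACT1, a measure of RNA integrity, was 4.81, 3.21 and 9.79 in replicates 1 to 3 before LiCl, and 2.41, 5.67, 2.66 and 2.53 at 20, 40, 60 and 140 min. That of TBP was 5.74, 5.18 and 6.76 before LiCl and 7.54, 6.34, 3.58 and 5.44 at those times. The 25S ribosomal RNA signal was 152, 4201 and 277 before LiCl and 4066, 3323, 896 and 2194 after it.

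Across the 4 LiCl arrays, genes of stress protection and reserve carbohydrates were higher and genes that build ribosomes were lower than before LiCl. Tested as lists with an estimated correlation between genes, the general stress genes alone passed. The call covered 1600 genes (29.6% of those tested), of which 707 were higher and 893 lower, and 965 of them changed at least 2-fold (440 higher, 525 lower; limma, adjusted p under 0.05). In 931 genes all 4 LiCl arrays lay above, and in 1127 genes below, all 3 arrays before LiCl, where chance gives 5.71% of genes for both directions together. The count was 936 without replicate 1 and 1009 without replicate 3 of the arrays before LiCl, and 634 without the pair of arrays with the highest ACT1 ratio (replicate 3 before LiCl and 40 min), an alternative chosen after the data had been seen.

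**Figure D1:**
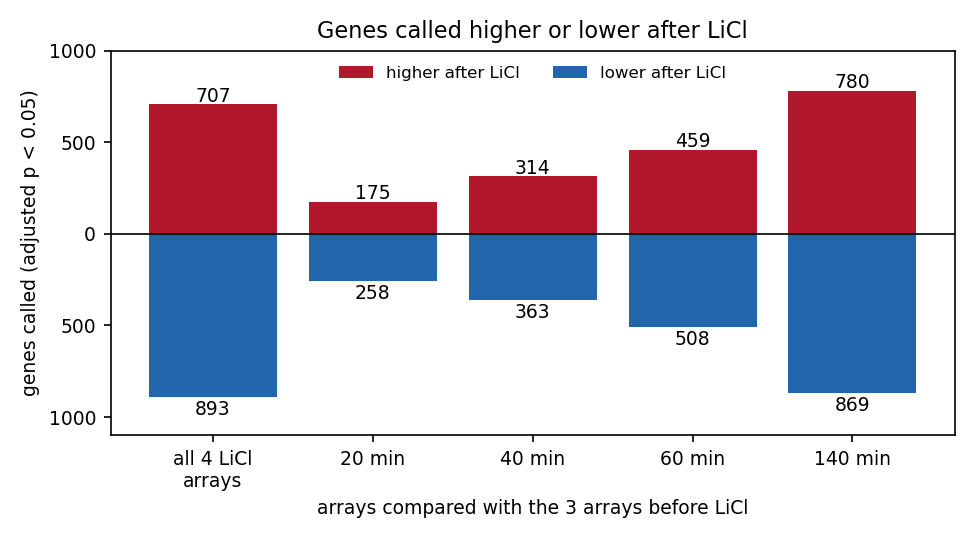
Number of genes called (y axis) in the comparison of all 4 LiCl arrays, and of the array at each time, with the 3 arrays before LiCl (x axis). Red bars count genes higher after LiCl and blue bars, drawn downward, genes lower after LiCl, from 175 higher and 258 lower at 20 min to 780 higher and 869 lower at 140 min.

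The largest rise was that of SIP18, which encodes a hydrophilin of osmotic and desiccation stress, from 108 ± 24.1 (SD, n = 3) to 4097 on average, a log2 change of 5.03 ± 0.49 (SE; adjusted p = 4.79e-05). HSP30, a plasma membrane heat shock protein that restrains the proton pump, stood at 737 ± 22.0 (SD, n = 3) before LiCl and between 10659 and 13862 in every LiCl array (log2 change 3.96 ± 0.18 SE, adjusted p = 3.27e-07). SHH3, a mitochondrial protein similar to a succinate dehydrogenase subunit, rose by 4.23 on the log2 scale, IRC4 by 3.96, FMP16 by 3.81 and ULI1, an unfolded protein response gene, by 3.69. CTT1, the cytosolic catalase, rose 10.8-fold from 71.7 ± 27.9 (SD, n = 3). The uncharacterised genes YCL048W-A and YKL107W rose by 3.90 and 3.56 on the log2 scale from intensities near the floor of 20.9, and these folds are understated for that reason. With a floor at the 40th percentile the log2 changes of YCL048W-A, YKL107W, SHH3 and IRC4 were 1.90, 1.55, 3.54 and 2.94. Without the 20 min array those of SHH3 and ULI1 were 5.03 and 4.45. The remaining genes among the 12 largest rises were TKL2 (3.66), GND2 (3.44) and SOL4 (3.43), isoenzymes of the pentose phosphate pathway. The probe set of TKL2 is marked as shared with a similar gene. A plain probe set of TKL2 gave 4.48.

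The largest fall was that of NSR1, the yeast nucleolin, from 1867 ± 342 (SD, n = 3) to 189 on average, or 9.90-fold (log2 change -3.31 ± 0.23 SE, adjusted p = 5.95e-06). Other genes of ribosome assembly among the 12 largest falls were the RNA helicase DBP2 (log2 change -2.57), ENP1 (-2.50), the fibrillarin gene NOP1 (-2.45), BRX1 (-2.44) and UTP13 (-2.44). AAH1, which encodes adenine deaminase, fell from 462 ± 27.7 (SD, n = 3) to 76.2 on average, or 6.22-fold. FET3, the multicopper oxidase of high-affinity iron uptake, had an intensity of 2926 ± 199 (SD, n = 3) before LiCl and reached 270 at 140 min, with a log2 change of -2.51 ± 0.46 (SE) over the 4 arrays. RFU1, an inhibitor of a deubiquitinating enzyme, fell by 2.45 on the log2 scale, the regulator HMS2 by 2.43, the tRNA methyltransferase gene TRM11 by 2.43 and SFG1, a regulator of growth form, by 2.38. The falls of HMS2, RFU1 and SFG1 depend on the floor. With it at the 40th percentile their log2 changes were -0.92, -1.20 and -1.74 (HMS2 -3.18 with a floor at the 10th percentile).

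Of the 29 gene lists, 14 passed the camera test in the grouped comparison, 6 of them toward higher and 8 toward lower levels. With an estimated correlation between genes the general stress list alone passed. That correlation is estimated from a spread that holds the time course too. With the slope on log2 time in the model, ribosome biogenesis alone passed instead. The general stress list then had a camera adjusted p of 0.0536. That alternative was added after the data had been seen. The list medians below are log2 changes in the 4 LiCl arrays. Counts are of called genes, followed where different by the count adjusted over the list alone. Where a named gene lost its call in 5 or more alternatives, their number is given. Of the 29 named genes that were not called, 17 were called in 1 to 4 alternatives.

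Genes of ribosome biogenesis, the assembly of ribosomes in the nucleolus, fell as a group: 86 of 90 tested members were called lower and none higher (87 lower adjusted over the list alone), with a median of -1.63 (camera adjusted p = 3.93e-33; adjusted p = 0.0629 with an estimated correlation). Of the cytosolic ribosomal protein genes, 70 of 81 were called lower and none higher (78 adjusted over the list alone), with a median of -1.02 (adjusted p = 9.20e-18; adjusted p = 0.292 with an estimated correlation). RPS14B fell by 1.94, RPS26B by 1.93 and RPS27A by 1.85 on the log2 scale. RPL7B, with a marked probe set, had a log2 change of -2.03 ± 0.51 (SE), but its arrays before LiCl spread widely (525 ± 498, SD, n = 3). Without replicate 2 the change was -1.29. With the ACT1 ratio or the 25S ribosomal RNA signal as a covariate the change was -2.69 or -2.62. Of 31 genes of RNA polymerases I and III, which make ribosomal and transfer RNA, 19 were called lower (21 adjusted over the list alone; median -0.93, adjusted p = 1.66e-07; adjusted p = 0.0887 with an estimated correlation). Among them the polymerase I subunits RPA43, RPA49, RPA34 and RPA190 fell by 2.26, 2.16, 2.05 and 1.95 on the log2 scale.

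Translation factors, aminoacyl-tRNA synthetases, nucleotide and amino acid biosynthesis, and G1/S with DNA replication were the other lists that passed toward lower levels. None of the 5 did so with an estimated correlation. Of 32 translation factors, 22 were called lower (24 adjusted over the list alone; median -0.90, adjusted p = 6.69e-07; adjusted p = 0.0629 with an estimated correlation), with NIP1, TEF4, TIF5 and RPG1 at log2 changes of -1.48, -1.46, -1.45 and -1.43. Of 18 aminoacyl-tRNA synthetases, 12 were called lower (15 adjusted over the list alone; median -0.82, adjusted p = 1.59e-05; adjusted p = 0.242 with an estimated correlation), with KRS1, MES1, CDC60 and SES1 at -1.34, -1.25, -1.14 and -1.14. KRS1 was dim, below the filter at 3 times the floor, and was tested in 19 of 21 alternatives. Nucleotide biosynthesis had 23 of 35 genes called lower and 4 higher (24 and 4 adjusted over the list alone; median -0.82, adjusted p = 3.48e-05; adjusted p = 0.0629 with an estimated correlation). Besides AAH1, the CTP synthase gene URA7 fell by 2.08 and the phosphoribosyltransferase gene HPT1 by 2.04 on the log2 scale, whereas URA10, the minor orotate phosphoribosyltransferase, rose by 2.90. Of 46 genes of amino acid biosynthesis, 17 were called lower and 2 higher, also when adjusted over the list alone (median -0.49, adjusted p = 0.00211; adjusted p = 0.116 with an estimated correlation). LEU9, GDH1, ILV5 and BAT1 had log2 changes of -1.78, -1.53, -1.38 and -1.15. In the list of G1/S and DNA replication 12 of 23 genes were called lower (19 adjusted over the list alone; median -0.84, adjusted p = 1.50e-06; adjusted p = 0.271 with an estimated correlation), among them POL30 (log2 change -1.59), RNR1 (-1.55), CDC45 (-1.42) and POL2 (-1.38).

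Stress and storage genes shifted upward. Of the 38 genes of the general stress response, 30 were called higher and 1 lower (34 and 1 adjusted over the list alone), with a median of 1.72 (adjusted p = 7.26e-19; adjusted p = 0.0275 with an estimated correlation). Besides SIP18 and CTT1, the small heat shock protein gene HSP26 rose by 3.20 and MSC1 by 3.18 on the log2 scale. Of 17 genes of trehalose and glycogen metabolism, 11 were called higher and none lower (12 adjusted over the list alone; median 1.21, adjusted p = 1.13e-07; adjusted p = 0.194 with an estimated correlation). They included glycogen synthase GSY2 and the debranching and phosphorylase genes GDB1 and GPH1, with log2 changes of 2.19, 1.77 and 1.75, and PIG2, with 2.08 (1.36 with a floor at the 40th percentile). Of 26 chaperones, 11 were called higher and 1 lower (12 and 1 adjusted over the list alone; median 0.42, adjusted p = 0.00282; adjusted p = 0.242 with an estimated correlation), with SSA4, SSE2, SSA3 and HSP42 at 2.64, 2.50, 2.11 and 1.95. The call of SSA3 was lost in 6 of 21 alternatives, among them those without replicate 1 or 3 of the arrays before LiCl.

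Gluconeogenesis with two-carbon metabolism, fatty acid oxidation and the proteasome were the other lists that passed toward higher levels. None of the 3 did so with an estimated correlation. In the list of gluconeogenesis and two-carbon metabolism 7 of 15 genes were called higher and none lower (10 higher and 1 lower adjusted over the list alone; median 0.78, adjusted p = 0.000314; adjusted p = 0.0629 with an estimated correlation). The carnitine acetyltransferase genes CAT2 and YAT1, isocitrate lyase ICL1 and malate dehydrogenase MDH2 had log2 changes of 1.84, 1.66, 1.37 and 1.29. Of 12 genes of fatty acid oxidation, 6 were called higher (6 higher and 1 lower adjusted over the list alone; median 0.59, adjusted p = 0.000915; adjusted p = 0.0629 with an estimated correlation), with CRC1, FOX2, SPS19 and POT1 at 1.68, 1.67, 1.17 and 1.16. Of 32 proteasome genes, 1 was called higher and none was called when adjusted over the list alone, although the list passed with a median of 0.21 (adjusted p = 0.0165; adjusted p = 0.292 with an estimated correlation, and adjusted p = 0.0744 after quantile normalization). That gene was PRE1, at 0.60 ± 0.20 (SE), whose call was lost in 10 of 21 alternatives, followed by PUP2, RPN11 and RPT3 at 0.57, 0.53 and 0.45, which were not called.

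Galactose is taken up by the permease GAL2 and converted to glucose phosphate by GAL1, GAL7, GAL10 and phosphoglucomutase, an enzyme that lithium inhibits. None of the structural genes GAL1, GAL2, GAL7 and GAL10 was called. GAL1 had an intensity of 6423 ± 473 (SD, n = 3) before LiCl and 5947 on average after it, with a log2 change of -0.14 (95% interval -0.60 to 0.32, adjusted p = 0.646). The log2 changes of GAL2, GAL7 and GAL10 were -0.18 (-0.58 to 0.22), -0.26 (-0.64 to 0.12) and -0.22 (-0.68 to 0.24), and all 4 of these changes turned positive after quantile normalization, at up to 0.16. The regulators GAL3, GAL4 and GAL80 had log2 changes of 0.17, 0.24 and -0.16 and were not called. PGM2, the major phosphoglucomutase, rose from 2142 ± 253 (SD, n = 3) to between 3983 and 4318 in the LiCl arrays, or 1.94-fold (log2 change 0.96 ± 0.17 SE, adjusted p = 0.00196). PGM1, the minor isoenzyme, had a log2 change of -0.57 ± 0.22 (SE) and was not called (adjusted p = 0.0717; called in 3 of 21 alternatives, with adjusted p down to 0.0264). Neither was the cyclin gene PCL10 (0.48, adjusted p = 0.128). UGP1, UDP-glucose pyrophosphorylase, had a log2 change of 0.68 ± 0.22 (SE) with an adjusted p of 0.0374, and its call was lost in 11 of 21 alternatives (adjusted p = 0.00950 to 0.181). The list of galactose utilisation did not pass: 2 of its 12 genes were called higher and none lower (1 higher adjusted over the list alone), and its median (-0.11) and mean (0.08) differ in sign (adjusted p = 0.600).

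**Figure D2:**
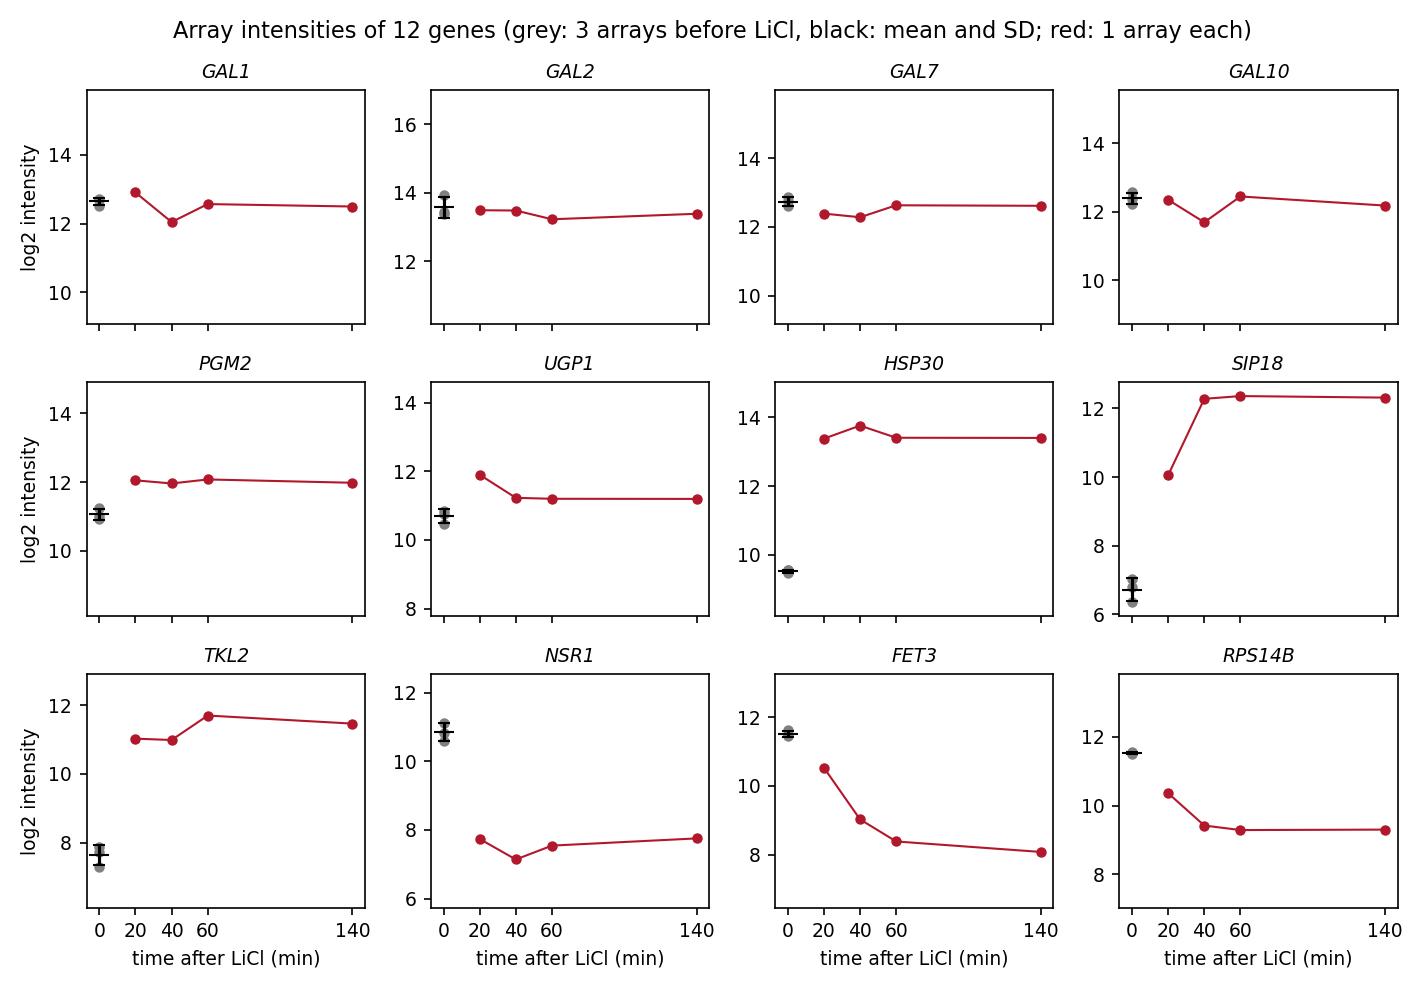
Log2 intensity (y axis) of 12 genes against time after LiCl in min (x axis), on axes of equal span. Grey points are the 3 arrays before LiCl, black bars their mean and SD, and red points the single arrays at 20, 40, 60 and 140 min; PGM2 stands about 1 log2 unit higher at each time, and GAL1, GAL2, GAL7 and GAL10, which were not called, stay within 1 log2 unit of their mean before LiCl.

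MET22, INM1 and HAL1, genes tied to lithium or salt, were not called in the grouped comparison. MET22, a lithium-sensitive phosphatase of sulfur assimilation, had a log2 change of 0.52 ± 0.20 (SE; adjusted p = 0.0629), and was called in 2 of 21 alternatives, with adjusted p down to 0.0124. INM1, inositol monophosphatase, had a log2 change of 0.81 ± 0.41 (SE; adjusted p = 0.159; 0.00116 without the 20 min array, and called in 2 of 21 alternatives) over the 4 arrays, with -0.58 at 20 min and 1.10, 1.25 and 1.48 at 40, 60 and 140 min, and was called at those 3 later times (adjusted p = 0.0443, 0.0276 and 0.0128). HAL1 had a log2 change of 0.29 (adjusted p = 0.531). In the list of cation transport and tolerance 2 of 20 genes were called, the calcineurin regulator RCN1 (1.27, call lost in 7 of 21 alternatives) and the calcium pump PMC1 (0.95), and TRK2 and SAT4 at 0.68 and -0.64 were not (list median 0.12, adjusted p = 0.376). In the list of glycerol and osmotic response 3 of 17 genes were called higher and 1 lower (3 and 0 adjusted over the list alone; median 0.37, adjusted p = 0.106). The called members included the glycerol phosphate dehydrogenases GPD2 (1.47, call lost in 6 of 21 alternatives) and GPD1 (1.28) and DAK1 (0.82). DAK2, at the floor in all arrays before LiCl, was called at 140 min alone, where it was at least 15.5-fold higher.

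The other lists did not pass the test in the grouped comparison. In 4 of 24 alternatives each, the lists of glycolysis and fermentation and of G2/M did pass. Of 20 genes of glycolysis and fermentation, 5 were called higher (median 0.13, adjusted p = 0.0805; adjusted p = 0.00203 and median 0.39 after quantile normalization), with PDC6 (call lost in 6 of 21 alternatives; 0.76 with a floor at the 40th percentile), PYK2, TDH1 and GLK1 at log2 changes of 1.70, 1.53, 1.39 and 1.19. Of 11 hexose transporters and sensors, HXT5 alone was called, at 3.09 ± 0.27 (SE), with HXT1, HXT3 and RGT2 at 0.56, 0.51 and 0.20 (list median 0.11, adjusted p = 0.254). The pentose phosphate list had 4 genes called higher and 3 lower among 11 (4 and 4 adjusted over the list alone), with a median of -0.40 but a mean of 0.73 (adjusted p = 0.354); its risers were TKL2, GND2, SOL4 and NQM1 (2.39). Sulfur assimilation and methionine had 4 of 26 genes called higher and 1 lower (median 0.10, adjusted p = 0.272), with SAM1, MET28, STR3 and MET32 (call lost in 6 of 21 alternatives) at -1.28, 1.15, 1.06 and 0.71. The tricarboxylic acid cycle list had 1 of 17 genes called higher, CIT3 (1.88), and 2 lower, IDP1 (-0.75, call lost in 5 of 21 alternatives) and IDH1 (-0.65, lost in 13), or 1 and 1 adjusted over the list alone (median -0.25, adjusted p = 0.305). LSC1 at -0.47 was not called.

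Of 35 genes of the respiratory chain and ATP synthase, 3 were called higher and 3 lower (3 and 1 adjusted over the list alone; median -0.19, adjusted p = 0.408). The risers were CYC7 (3.31), NDE2 (2.79) and COX5B (1.46, or 0.65 with a floor at the 40th percentile and not called), isoforms or alternative enzymes of the chain, and INH1 (-0.80) was among the genes called lower, with its call lost in 12 of 21 alternatives. The cell wall list had 6 of 26 genes higher and 4 lower (9 and 5 adjusted over the list alone; median 0.27, adjusted p = 0.366), with PIR3 (2.72, or 2.08 without the 140 min array), SLT2 (1.16), GAS1 (-1.15) and KDX1 (1.04, call lost in 12 of 21 alternatives; 0.35 with a floor at the 40th percentile). The ergosterol list had 1 of 23 higher and 3 lower (0 and 2 adjusted over the list alone; median -0.22, adjusted p = 0.317), with ERG3 at -1.29 and ERG5 at -1.17 called, and ERG4 at -0.91 and ERG6 at -0.72 not. The list of inositol and phospholipid biosynthesis had 1 of 18 higher and 3 lower (median -0.01 and mean -0.08, against a camera direction toward higher, adjusted p = 0.904), and the fallers were ITR1 (-1.30), PSD1 (-1.20, call lost in 9 of 21 alternatives) and CPT1 (-0.82, lost in 6). Among 13 genes of the G2/M list, CDC5 (-1.23), BUD4 (-1.16, marked probe set), SWI4 (-0.92) and BUD3 (-0.91) were called lower, with the last 3 calls lost in 7 of 20, 7 of 19 and 10 of 21 alternatives (median -0.51, adjusted p = 0.0664; adjusted p = 0.0441 without replicate 3 before LiCl and 0.0402 without the 20 min array). SWI4 is known as a regulator of G1/S genes, and without it the median was -0.44 (adjusted p = 0.106). Of 4 genes tested of the histone list, which holds the linker histone HHO1 and the variant HTZ1 beside core histones, HTB2 (-0.90) was called and HHO1 (-0.87), HTZ1 (-0.62) and HTB1 (-0.36) were not (3 lower adjusted over the list alone; median -0.75, adjusted p = 0.0934). Of 14 meiosis genes, SPO11 (1.21) and HOP1 were called higher and SPS4 (-1.06) lower, with REC8 at 0.90 (0.30 with the ACT1 ratio as a covariate) not called (median 0.32, adjusted p = 0.176). Over the 24 alternatives the median of this list ranged from 0.19 to 1.22, and the list passed camera in 1 (adjusted p = 0.0373). HOP1, at the floor in all arrays before LiCl, was at least 5.02-fold higher.

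The comparison of single times with the arrays before LiCl asked how early these changes appeared. At 20 min 433 genes were called (175 higher, 258 lower), at 40 min 677 (314 and 363), at 60 min 967 (459 and 508) and at 140 min 1649 (780 and 869). The largest rises called at 20 min were those of HSP30, YNL194C, SOL4 and RTN2, with log2 changes of 3.85, 3.78, 3.64 and 3.58, and the largest falls those of AAH1, NSR1, REI1 (marked probe set) and ENP1, with -3.17, -3.11, -3.09 and -3.08. SIP18 led at 40 min with 5.56, ahead of HSP30 (4.23), YCL048W-A (4.16) and SHH3 (4.08), and RPF2 was among the largest falls there (-2.87), with NSR1 (-3.71), HMS2 (-2.96) and ENP1 (-2.89). At 60 min SIP18 (5.64), SHH3 (5.01), ULI1 (4.57) and IRC4 (4.35) rose most and NSR1 (-3.31), FET3 (-3.13), HMS2 (-2.96) and TRM11 (-2.96) fell most. At 140 min SHH3 led with 5.98, ahead of SIP18 (5.59), ULI1 (5.30) and IRC4 (5.20), and the largest falls were those of FET3 (-3.44), SFG1 (-3.27), RFU1 (-3.24) and NSR1 (-3.10). An F-test over all times called 966 genes. When any 1 of the 3 arrays before LiCl was left out, no gene was called by the F-test or at 20 or 40 min. At 60 min 0 to 387 genes were then called, and at 140 min 265 to 1164. Without the filter on dim probe sets 9 genes were called at 20 min.

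Over lists and times, 60 of 116 tests passed at the preset correlation of 0.01. None passed with an estimated correlation (smallest adjusted p = 0.177), a test chosen after the data had been seen. The estimated correlation rested on the 2 residual degrees of freedom from the arrays before LiCl, so that test had little power. Its outcome cannot decide whether lists shifted at single times. The ribosome biogenesis list had a median log2 change of -1.87 at 20 min and of -1.57, -1.50 and -1.52 at 40, 60 and 140 min. The ribosomal protein list had medians of -0.52, -1.01, -1.08 and -1.56 at the same times, and 7, 29, 43 and 69 of its genes were called lower. The trehalose and glycogen list had its highest median at 20 min (1.70, against 1.30, 1.17 and 1.12 later). At the preset correlation the tricarboxylic acid cycle and respiratory chain lists passed at 140 min, with medians of -0.63 (adjusted p = 0.00714) and -0.59 (adjusted p = 0.00680), and the list of G2/M did so with -1.09 (adjusted p = 0.0246; 0.0415 without SWI4). Meiosis genes passed at 60 min (0.63, adjusted p = 0.00676) and the glycerol list at 20 min (0.28, adjusted p = 0.0343). The galactose list passed at none of the 4 times.

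**Figure D3:**
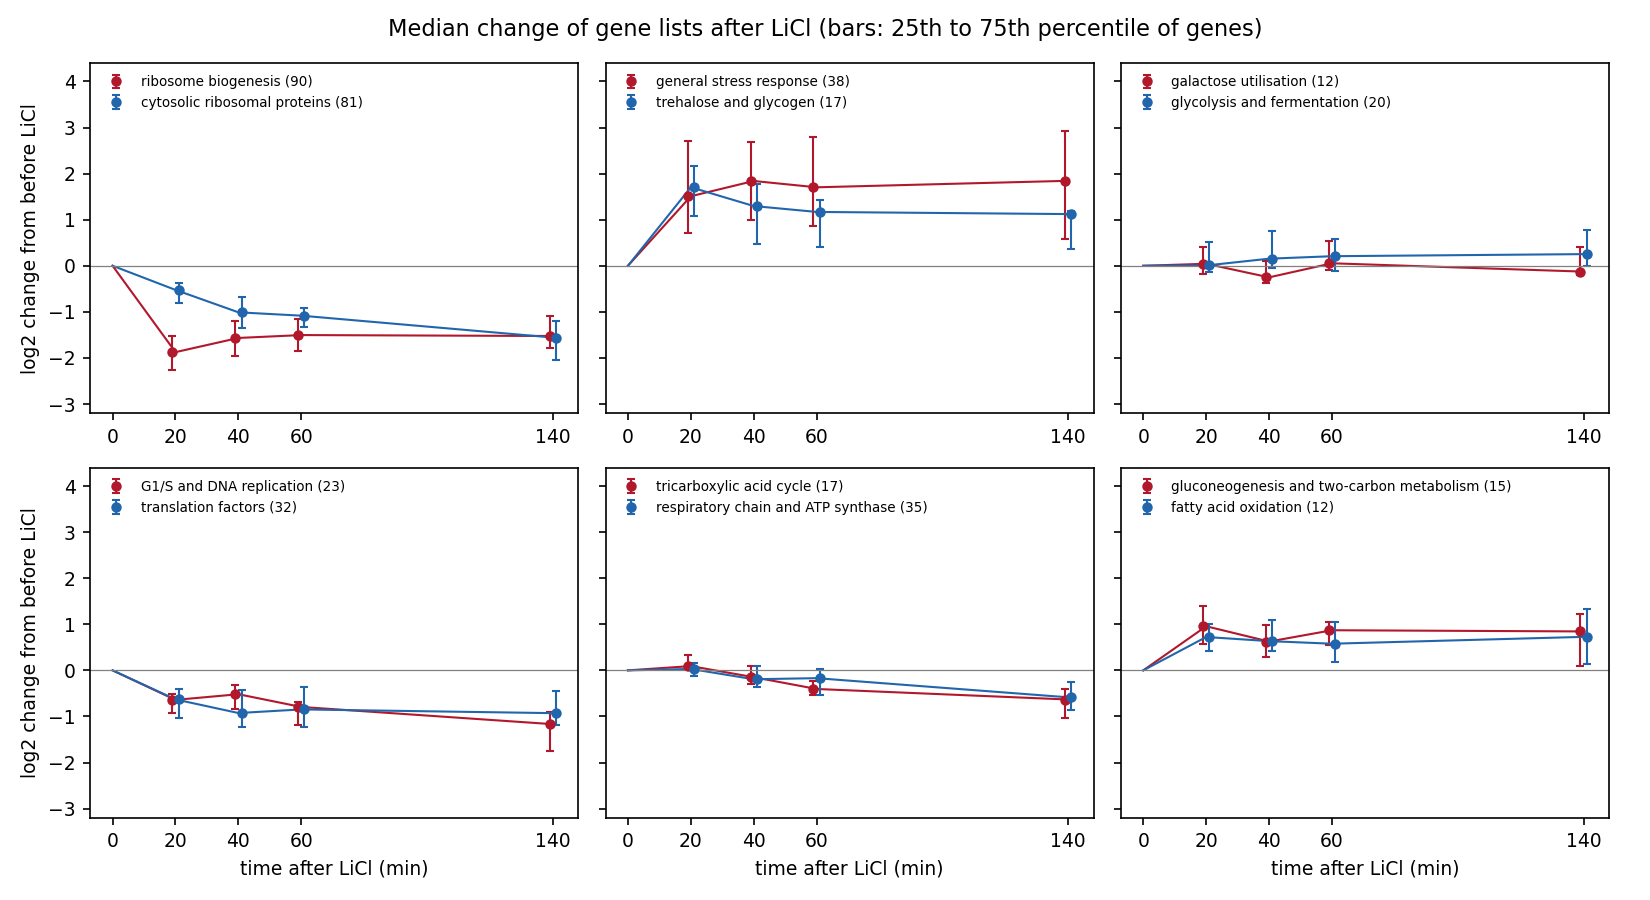
Median log2 change from before LiCl (y axis) of 12 gene lists against time after LiCl in min (x axis), with the number of genes tested in parentheses. Bars span the 25th to 75th percentile over genes, and points of both lists in a panel are set slightly apart; the ribosome biogenesis list is at -1.87 at 20 min, when the ribosomal protein list is at -0.52.

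The direct contrast of 140 against 20 min, which does not use the levels before LiCl, called no gene (limma, smallest adjusted p = 0.0599), although 1280 genes had an unadjusted p under 0.05. It compares 1 array with 1 array on the spread of the arrays before LiCl. After quantile normalization it called 125 genes, and with an offset in place of the floor 260.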

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

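The slope on log2 time within the LiCl arrays, its gene list tests, the tests of gradual change in the culture, the fits with the ACT1 and TBP ratios and the 25S ribosomal RNA signal, and the tests of bright genes by direction were chosen after the data had been seen. Of 173 values of lists and named genes over the 4 LiCl arrays, 14 had an array set apart from the other 3, where chance sets apart about 1 in 20. At 20 min these were the ribosome biogenesis list, with a median log2 change of -1.87, SIP18 (3.33), YCL048W-A (2.97), UGP1 (1.20), SAM1 (-0.58), CDC5 (-0.70), RPS14B (-1.17), RPS26B (-0.88) and MET22 (0.15). At 40 min HSP30 stood apart with 4.23, and at 60 min KRS1 with -1.19 and STR3 with 1.36. At 140 min the ergosterol list stood apart with a median of -0.44, and DAK2 with 3.96, a lower bound because it was at the floor before LiCl.

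With a slope per doubling of time in the model, 211 genes rose and 194 fell between 20 and 140 min (limma, adjusted p under 0.05), and the number called was 19 without the 20 min array and 11 without the 140 min array. Of the 29 lists, 9 passed the camera test for the slope. Their median slopes were -0.36 for cytosolic ribosomal proteins, -0.29 for the tricarboxylic acid cycle, -0.25 for trehalose and glycogen, -0.23 for the respiratory chain and ATP synthase, -0.23 for G2/M, -0.17 for aminoacyl-tRNA synthetases, -0.17 for G1/S and DNA replication, 0.23 for meiosis and sporulation and 0.20 for ribosome biogenesis. None passed with an estimated correlation (lowest adjusted p = 0.231). Without the 20 min array the unadjusted p was 0.123 for trehalose and glycogen, 0.119 for G2/M, 0.181 for meiosis and sporulation and 0.126 for ribosome biogenesis, and without the 140 min array it was 0.0748 for G1/S and DNA replication.

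Probe sets outside the gene tests also differed between the groups. Of 1333 probe sets without a gene in the annotation, 99 were higher and 90 lower after LiCl, and of 277 with several genes, 53 were higher and 54 lower. Of 35 array controls tested, none was called.

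Of the 35 splits of the 7 arrays into 3 and 4, 1, the real one, called as many as 1600 genes (highest other 937, with the 40, 60 and 140 min arrays against the rest). This argues against noise between single arrays as far as 35 splits can. The labels do not say which arrays share a culture, so the splits cannot exclude a chance difference between cultures. With the ACT1 ratio as a covariate the median shift of the ribosome biogenesis list was 0.970 of its value (bootstrap 95% interval 0.918 to 1.03) and that of the stress list 1.03, and 938 genes were called. The 3' to 5' ratio of TBP, which orders the arrays differently (highest, 7.54, at 20 min), left at least 1.00 of both shifts (0.959 to 1.02 for the stress list; 1509 genes called), and the 25S ribosomal RNA signal, from 152 to 4201 over the arrays, left 0.995 or more (0.923 to 1.06 for ribosome biogenesis; 940 genes called). The median shifts of both lists thus kept nearly their size with each covariate. The intervals are over genes and hold no spread between the 7 arrays. RNA integrity and ribosomal RNA signal are therefore not excluded as a source of these shifts or of single calls. For ribosome biogenesis the fall did not grow from 20 to 140 min: the median slope was 0.20 (0.16 to 0.25 over genes). It stayed positive without any 1 LiCl array, from 0.13 without 20 min to 0.29 without 140 min. A fall that grows with the age of the culture would give a negative slope. The positive slope did not pass camera with an estimated correlation (p = 0.0707), a condition set after the slope had been seen. Its interval is over genes and holds no spread between arrays. The test therefore cannot decide whether the age of the culture contributed. For ribosomal proteins a fall that grows with age cannot be told apart from LiCl, because 0 arrays after 0 min lack LiCl. An effect of the addition itself stays open for both lists.

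The ribosomal protein genes had a falling slope (-0.36, bootstrap 95% interval -0.39 to -0.31), while ribosome biogenesis genes were at their lowest median at 20 min. Genes matched in brightness (10 per ribosomal protein gene) had a slope of 0.0654 times that of the ribosomal protein genes (0.0300 to 0.121), which argues against brightness. The 51 ribosomal protein genes with plain probe sets had 0.993 times the slope of the 30 with marked ones (0.742 to 1.21), so the slope did not come from the marked probe sets alone. Paralogs that fall together would give like slopes with or without shared signal, so the ratio cannot exclude such signal. A candidate explanation is that the transcripts differ in stability or in the timing of their repression; neither was tested, and the slope did not pass with an estimated correlation (adjusted p = 0.304).

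The structural galactose genes were among the brightest on the arrays, and a saturated probe set could hide a change. Of the 165 other genes at least as bright as the dimmest of GAL1, GAL2, GAL7 and GAL10, 54 were called, 1.11 times the share of all tested genes (exact binomial 95% interval 0.866 to 1.37), but 46 of these were lower and 8 higher, so this count cannot speak for both directions. The tests by direction were first run without the ribosomal protein and ribosome biogenesis lists, where the shares called lower and higher were 0.582 (0.284 to 1.03) and 0.485 (0.213 to 0.926) times those of the other tested genes, and were widened to all 165 genes after these values had been seen. Over all 165 the share called lower was 1.69 times that of all tested genes (1.28 to 2.14), so falls could be called at this brightness. The ribosomal genes carry that result. Without them the interval of the share called lower holds 0.5, the bound set for the test, so a masked fall is not excluded. The share called higher was 0.371 times that of all tested genes (0.162 to 0.713), an interval that holds 0.5, the bound set for the test, so a masked rise stays open, and no biological explanation was tested.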

How the results depend on the processing

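Of 144 named genes, 115 were called, and 75 of these kept their call in every alternative run. No called gene or list changed direction. Of the 29 not called, 17 were called in some alternative: SAT4 in 4, ERG6, HTZ1, PGM1, PUP2 and RPN11 in 3, ERG4, HHO1, INM1, MET22 and RPT3 in 2, and DAK2, HTB1, HXT1, LSC1, REC8 and TRK2 in 1. The fold change moved by over 1.5 times in some alternative for 18 named genes, 12 of them with a floor at the 40th percentile. The 14 lists that passed did so in every alternative chosen before the data were examined but estimated correlation, where 1 list passed, and quantile normalization, where glycolysis and fermentation took the place of the proteasome. The number of lists was also 1 in an alternative added after the data had been seen, estimated correlation with the slope in the model, and that list was ribosome biogenesis. The cause of the changes below was not tested unless given. Leaving out an array before LiCl lowers the residual degrees of freedom of both fits, to 1 in the fit by time. Leaving out each of the 7 arrays in turn gave 936 to 1981 genes changed in the LiCl arrays, 0 to 1181 at any time (0 whichever array before LiCl was left out) and 14 to 16 lists. For single times only the 3 arrays before LiCl were left out in turn, which gave 0 to 0 genes at 20 min, 0 to 0 at 40 min, 0 to 387 at 60 min, 265 to 1164 at 140 min and 0 to 0 that differ between 20 and 140 min. In added alternatives, leaving out the arrays before LiCl 3 and 40 min gave 634 genes in the LiCl arrays, 0 at any time, 0 at 20 min and 388 at 60 min. The ACT1 ratio as a covariate gave 938 genes in the LiCl arrays and the 25S ribosomal RNA signal as a covariate 940, both also added. Of the 60 list tests by time that passed, 0 did so with an estimated correlation, again an added alternative. A floor at the 40th percentile gave 531 genes at any time, 252 at 20 min and 30 between 20 and 140 min. Without a filter on dim probe sets the counts were 221 at any time, 9 at 20 min, 269 at 40 min, 506 at 60 min and 28 between 20 and 140 min. The contrast of 140 against 20 min, with 0 calls as reported, called 125 genes after quantile normalization, 7 with a floor at the 10th percentile, 260 with an offset, 227 with a filter at 3 times the floor and 10 with plain probe sets alone. All other alternatives left the counts within 1.5 times those reported. No paired analysis was possible because the labels do not link any array after LiCl to a particular one of the 3 arrays before it.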

Other observations

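The gene groups described here, and their tests, were chosen after the data had been seen. For iron supply, phosphate starvation and folding in the endoplasmic reticulum, some members had been seen before the group was made, so the tests below leave those out. The members left were read on the same arrays and may vary together with those seen. These tests are therefore not independent of how the groups were chosen. Of 22 genes of iron uptake or otherwise tied to iron supply, FET3 among them, 9 were called lower and none higher (median log2 change -0.62). Of the 11 that act in iron uptake at the cell surface, 6 were called lower, all of them members seen before the group was made. FRE3, the member of the 11 not seen before, was not called (limma, adjusted p = 0.215). Of the 12 members not seen before, CCC2, ISU2 and VHT1 were called lower; these encode a copper transporter, an iron-sulfur scaffold and a biotin transporter (median of the 12 -0.53; camera p = 0.00974, p = 0.203 with an estimated correlation). The iron permease gene FTR1 fell by 1.74, the reductase gene FRE1 by 1.67 and the siderophore transporter gene SIT1 by 1.33 on the log2 scale. The medians of all 22 were -0.35, -0.58, -0.89 and -1.06 at 20, 40, 60 and 140 min. Genes of folding and quality control in the endoplasmic reticulum moved the other way, with 12 of 23 called higher and none lower (median 0.62). Of the 19 not seen before, 10 were called higher (camera p = 6.88e-05, p = 0.225 with an estimated correlation). ERO1 and EUG1, which act in disulfide bond formation, rose by 2.04 and 2.01, the nucleotide exchange factor gene SIL1 by 1.97 and LHS1 by 1.54 on the log2 scale. KAR2, the main chaperone of that compartment, was not called (0.48, adjusted p = 0.0715). Among 14 genes of phosphate starvation, 5 were called higher, with PHM8 at 3.05 and the phosphate transporter PHO84 at 2.60. Of the 9 not seen before, 1 was called, and they did not pass the camera test.

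Genes of the mitochondrial ribosome had median log2 changes of -0.08, -0.54, -0.74 and -1.32 at 20, 40, 60 and 140 min over 74 tested members. In the grouped comparison 24 of them were called lower. The 1 called higher was MRP8, taken in by its name and not known as a part of that ribosome. The hypothesis that these genes fall with time as a group came from some members seen among the steepest fallers, so it was tested on the 64 members not seen before. Their median slope per doubling of time was -0.39 (camera unadjusted p = 0.00180 with an estimated correlation). Without MRP8 it was -0.40 (unadjusted p = 0.00165). Of the 64 members, 20 were called falling by themselves. The lists fixed before the data were examined were judged for the slope on adjusted p instead. Among them the tricarboxylic acid cycle list had the lowest unadjusted p with an estimated correlation, 0.00796 (adjusted p = 0.231). The p of 0.00180 therefore cannot be set against their failure to pass. The 64 members were read on the same arrays as those that raised the hypothesis and may vary together with them. The test is therefore not independent of that choice. The values describe a fall of the group that grew from 20 to 140 min, which may follow LiCl or the age of the culture. The design has no array that separates LiCl from age.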
